A study of Homo sapiens with 172 samples.

How the data were processed

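Lamina contacts were measured by DamID in single KBM7 cells. Per the labels' protocols, methylation by the Dam-LaminB1 fusion was induced for 15 h with 0.5 nM Shield1, a ligand that stabilises the fusion protein. The smallest 2% of cells positive for both Fucci cell cycle markers were sorted singly. Their DNA was cut with DpnI, which cuts at methylated GATC, and adaptor-ligated fragments were amplified by PCR. Per the submitters' processing notes, reads were handled with cutadapt and Bowtie2 2.1.0 against hg19. How duplicate reads were treated and what the expectation was built from are not given in the sources used here.

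The deposited table holds, for each cell, the ratio of observed over expected reads in 30376 bins of 100 kb. It has a column for 168 of the 172 labelled samples, and samples 81, 82, 167 and 168 are not analysed here. Of the bins, 3792 carried no value and 170 were 0 in every column. The remaining 26414 covered bins were used. Chromosome 8 and part of chromosome 15 are among the bins without a value, and chromosome Y was left out of every step.

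Read numbers were worked back from the ratios. Within a bin the values of all columns are whole multiples of a common step times a factor per column, and 100% of values above 0 came out whole within 0.02. The expectation had the same step, with whole numbers from 1 to 592 per bin (median 316), and recovered reads never exceeded it. As a further check, the factor of a column times its reads lay between 0.714 and 1.08 of the median over the 168 columns, so that no column was off by a whole factor. Simulated data of the size of the real table gave back 99.995% of 1749892 values, with the unit right in every column. They were drawn around the recovered reads and divided by the recovered expectation, so they cannot show that the real units are right. A smaller simulated table of 5000 bins and 60 cells, with sites and depths set independently, gave back only 65.3%. The unit of 1 simulated cell was wrong, so the recovery was not reliable for that table. Whether size, sites or depths made the difference was not tested.

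Columns were compared by the correlation of log reads and by a chi-square per bin over bins with at least 10 reads in the 2 columns together. The design assumed 172 separate cells. Since the columns n and n + 86 held the same cell, their ratios were averaged, and all results are over 84 cells. PCR reads without molecular identifiers are not independent molecules, so intervals and read differences cover counting error only.

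A bin was in contact in a cell at a ratio of at least 1. Contact frequency was the percent of cells in contact, with classes under 20, 20 to 80 and at least 80%, and exact Clopper-Pearson 95% intervals for named bins. A frequency of 0 was given an upper limit of 3 cells out of 84. Coordination used bins of 20 to 80% and correlations over cells after subtraction of a linear fit on each cell's contact share. Runs and chromosome SDs were compared with 100 shuffles of cells within each bin, inside 7 groups of cells of similar contact share, and correlations with 100 shuffles over all cells. Since cells are not replicates, no p-value was made from cells, and shares of shuffles of cells describe the 84 cells at hand only. Correlations over chromosomes had two-sided permutation tests with 100000 resamples, and positions had exact sign tests over chromosomes. Without planted coordination, simulated cells gave a run quotient of 1.00, a chromosome SD quotient of 0.96 and a correlation of adjacent bins of 0.000135. These cells had the observed bin frequencies but no planted spread in depth or contact share. With a planted correlation of 0.36 in blocks, all bins at the same frequency, a plain correlation of neighbours within a block returned 0.362. The correction for contact share was not run on these blocks.

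Named regions followed a rule fixed before the data were examined: the 10 longest stretches at 80% or more, the 5 longest under 5%, and the 3 highest and 3 lowest chromosomes. The cells and chromosomes nearly without reads were chosen after their values were seen, at under 5% of at least 300 expected reads and at least 2 such chromosomes in a cell. Single chromosome ends, pairs across the stretch without signal (acrocentric chromosomes and 22:9 left out) the 12 chromosomes with pairs beyond 100 Mb taken alone, and reads in rarely contacted bins were also added after seeing the data. Coding genes were counted per chromosome from a GRCh38.p14 gene table, divided by the chromosome length in the file. None of its coordinates was set against the bins, so the planned correlation of gene number with contact over bins, contact frequencies of genes in the lists, and gene names for regions were not run. The lists were used by chromosome instead, without genes on chromosomes 8, 9, 22 and Y, which left out type I interferons. Alternatives planned before the data were examined were other cutoffs, scaling each cell by its mean, averaging 5 bins, odd or even cells, fewer or more bins, no X, and no correction for contact share. Others were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.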

Results

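Contacts of the genome with the nuclear lamina, the protein layer under the inner nuclear membrane, were mapped in single cells of KBM7, a near-haploid human leukaemia line. The labels put all 172 samples in 1 group, haploid cells of clone 5-5 that carried Dam methyltransferase fused to LaminB1. This fusion methylates adenines in DNA that comes near the lamina, and the methylated fragments are amplified and sequenced. With 1 clone, no separate cultures named and no second group, there was no test between groups. Standard deviations below are over cells and describe cell-to-cell variation, not replicate error. The values were observed over expected ratios in 100 kb bins, in hg19 coordinates, for 168 of the labelled samples. Chromosomes 9 and 22 appear as a joined pair, 9:22 and 22:9. Chromosome 8 and positions 61000001 to 89900000 of chromosome 15 carried no value, which leaves 22 chromosomes with values.

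Samples whose numbers differ by 86 held the same cell. Each of the 168 columns had its highest correlation with the column 86 numbers away, which gave 84 pairs. In 82 pairs the reads differed by less than the sampling noise, with a chi-square per bin under 1, whereas no other combination of columns out of 13941 was under 1 and the lowest was 1.34. The pairs of cells 54 and 56 were above 1, at 1.53 and 3.60, and were still each other's best match. The columns of a pair were therefore averaged and counted as 1 cell, named by the lower number, for n = 84. Read totals in the deeper column of a cell ran from 7134 to 418937, with a median of 63700. A ratio of 1 in a median bin stood for 2.66 reads in the median cell, and for under 1 read in 13 of the 84 cells.

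The first question was how much of the genome touches the lamina in a cell. A bin was called in contact at a ratio of at least 1. Cells had 27.8% ± 6.55 (SD, n = 84) of the 26414 covered bins in contact. The lowest share was 14.5% in cell 19, which was also the cell with the fewest reads in its deeper column. The highest was 42.4% in cell 74, which had 404825 reads in its deeper column, close to the highest of 418937. Of all values, 50.0% were 0, 22.2% lay between 0 and 1, and 27.8% were at least 1. In the 35 cells with at least 100000 reads, log2 ratios of values above 0 had a peak in the interval from 1 to 1.5, with 7.75% of all values, and a smaller one from -3.5 to -3, with 2.85%. Whole reads give steps at such low ratios, so the smaller peak was not shown to be a separate level of signal. Contact calls of the paired columns matched in a median of 93.2% of bins, against 74.1% for calls of different cells, made from averaged columns. The reads of most pairs differed by less than sampling noise. The paired columns are thus not independent, and their match does not measure how reproducible the calls are.

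The next question was which regions touch the lamina in most, some or few cells. Contact frequency, the percent of the 84 cells with a bin in contact, had a peak at the low end and another at 60 to 70%. Of the covered bins, 13822 (52.3%) were in contact in under 20% of cells, 12512 (47.4%) in 20 to 80%, and 80 (0.303%) in at least 80%. Of these 80 bins, 23 were on chromosome 6, 14 on chromosome 3 and 11 on chromosome 1. No bin was in contact in every cell. The highest frequency was 88.1%, or 74 of 84 cells (exact 95% interval 79.2 to 94.1%), at X:113600001 to 113700000 and at 6:124800001 to 124900000. Intervals cover counting error only. In shallow cells a missed contact and an absent one cannot be told apart. Cell 19, for example, had a read in 11.6% of bins in its deeper column. The highest frequencies may therefore be too low. They were also picked as the highest of all covered bins, which pushes them upwards, and the intervals do not allow for this choice. The size of the highest class depended on processing, with 0.0265% of bins when only the lower-numbered column of each cell was used and 6.20% at a cutoff of 0.5.

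**Figure D1:**
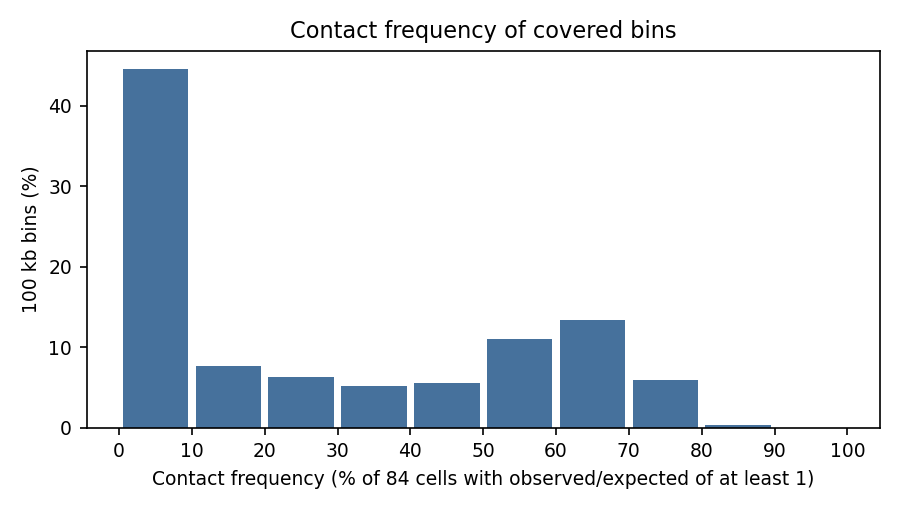
Bars give the percent of the 26414 covered 100 kb bins (vertical axis) in each interval of contact frequency (horizontal axis, percent of 84 cells with a ratio of at least 1). The interval from 0 to 10% holds 44.6% of bins, that from 30 to 40% holds 5.16%, and that from 60 to 70% holds 13.4%.

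The stretches contacted in at least 80% of cells were short. The longest were 1:218900001 to 219300000, with a mean frequency of 81.5%, 6:124600001 to 124900000, with 84.9%, and X:113500001 to 113800000, with 83.3%. Stretches of 0.2 Mb lay at 3:180100001 to 180300000, 6:146600001 to 146800000, 11:92000001 to 92200000, 1:215000001 to 215200000, 2:209800001 to 210000000 and 2:221100001 to 221300000, with means from 81.0 to 81.5%. The tenth by the naming rule was the single bin 1:187400001 to 187500000, at 86.9%. At a limit of 50% the longest stretch was 9:22 from 7300001 to 14300000, which is 7 Mb with a mean of 68.3%.

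Regions that met the lamina in few cells were longer. In all, 9699 bins (36.7%) were contacted in under 5% of cells, and 1636 bins were contacted in no cell, which allows a frequency of up to 3.57%. The longest stretches under 5% were 22:9 from 21900001 to 31000000, with a mean of 0.916%, chromosome 19 from 9300001 to 18400000, with 1.70%, chromosome 19 from 200001 to 9200000, with 1.59%, chromosome 1 from 17200001 to 26200000, with 1.98%, and chromosome 19 from 33100001 to 41400000, with 1.71%.

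Chromosomes differed widely in their contact with the lamina. Chromosome 4 had 37.8% ± 12.3 of its bins in contact, chromosome X 37.2% ± 11.2 and chromosome 18 33.6% ± 11.9 (SD, n = 84). At the other end stood 22:9 with 1.53% ± 1.79, chromosome 19 with 4.89% ± 4.13 and chromosome 17 with 8.44% ± 5.58. Chromosomes 18 and 19, which are of similar size and are known for low and high gene density, differed by 28.8 ± 12.5 percentage points, and chromosome 18 was higher in 82 of 84 cells. Chromosome X was above the rest of the genome by 9.96 ± 8.16 points, and higher in 73 of 84 cells.

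Over the 20 chromosomes with values that are not joined in the table, contact share fell with the number of coding genes per Mb (Pearson r = -0.80, two-sided permutation p = 2e-05, adjusted 8e-05) and Spearman's rho was -0.70 (p = 0.00093, adjusted 0.00186). Chromosome 15, with 510 of 1026 bins covered, entered with its full gene number and length, and r was -0.82 without it. Without chromosomes 19 and 17, which lie farthest from the median gene density, r was -0.61. Contact share rose with chromosome length (r = 0.55, p = 0.012, rho = 0.54, p = 0.0148, both adjusted to 0.0148), and r was 0.72 without chromosomes 1 and 2. These 4 coefficients formed the family for the Benjamini-Hochberg adjustment. In cells 1 to 29 and in cells 30 to 86, which differ in how their paired columns relate, the gene-density r was -0.85 and -0.77.

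**Figure D2:**
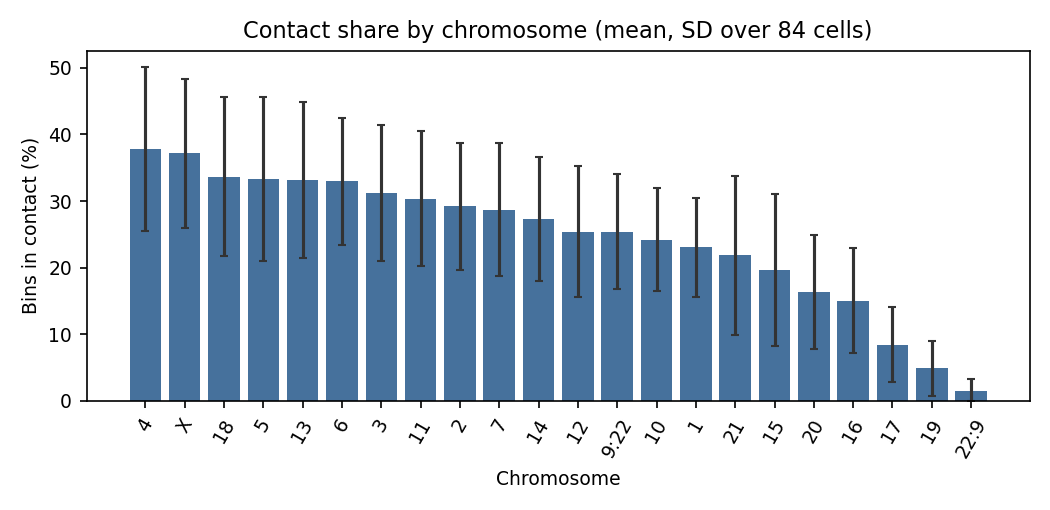
Bars give the mean percent of covered bins in contact (vertical axis) for each of the 22 chromosomes with values (horizontal axis, in falling order), and lines the SD over 84 cells, stopped at 0 below. Chromosome 4 is highest at 37.8% and 22:9 lowest at 1.53%.

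Chromosome ends were mostly away from the lamina. Bins within 2 Mb of an end had a mean contact frequency of 7.29%, against 25.2% in the rest of the same chromosomes, a difference of -17.9 ± 11.2 points (SD over 22 chromosomes). Ends were lower in 20 of 22 chromosomes (exact two-sided sign test, p = 0.000121), with chromosomes 3 and 22:9 as the exceptions. Of the 38 ends with values, 31 had a mean frequency under 10%. The start of chromosome 3, positions 1 to 2000000, stood apart at 62.9%. It was followed by the start of 9:22 at 34.2%, the end of chromosome 1 at 33.4%, the start of chromosome 18 at 32.4% and the end of chromosome 4 at 28.5%. Bins within 2 Mb of the longest stretch without signal, which lies at the centromere in most chromosomes, were higher than the rest in 9 chromosomes and lower in 13 (exact sign test, p = 0.523).

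Neighbouring bins tended to touch the lamina in the same cells. Runs of consecutive bins in contact had a mean length of 3.72 ± 1.52 bins (SD, n = 84), against 2.26 bins after cells of similar contact share were shuffled within each bin. The quotient was 1.62 ± 0.433, and 77 of 84 cells exceeded all of their 100 shuffles. Runs of at least 10 bins held 37.3% of contacts, against 10.3% after shuffling. The longest run, in cell 46, spanned 9.6 Mb. In cells 1 to 29 and cells 30 to 86 the quotient was 1.33 and 1.69. It was 1.39 in the 61 cells whose lower-numbered column was thinned to 30000 reads, against 1.60 in the lower-numbered columns of all cells. Whether depth made the difference between the sets of cells was not tested.

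This coordination faded with distance. Among the 12512 bins of intermediate frequency, the mean correlation over cells, corrected for each cell's overall contact share, was 0.415 ± 0.0415 for adjacent bins (SD over 21 chromosomes), 0.226 ± 0.0575 at 1.1 to 2 Mb, and 0.118 ± 0.0436 at 5.1 to 10 Mb. It was 0.0746 ± 0.0335 from over 20 to 50 Mb (20 chromosomes) and 0.0419 ± 0.0184 beyond 100 Mb (12 chromosomes), and 0.00306 between bins on different chromosomes. In these 12 chromosomes alone, the mean over chromosomes fell from 0.411 for adjacent bins to 0.0358 beyond 100 Mb. The correction draws the mean between chromosomes towards 0. Without it the correlations were 0.461 for adjacent bins, 0.285 at 1.1 to 2 Mb, 0.145 from over 20 to 50 Mb and 0.0769 between chromosomes. Shuffled cells gave means between -0.0025 and 0.00267 at every distance. Adjacent bins correlated at 0.337 in cells 1 to 29 and at 0.461 in cells 30 to 86. In a comparison added after seeing the data, pairs on the same side of the longest stretch without signal were not set apart by a sign test from pairs across it at matched distance (over 20 to 50 Mb: mean difference 0.0203 ± 0.0274, higher in 11 of 15 chromosomes, exact p = 0.118, adjusted 0.355 over 3 distances).

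**Figure D3:**
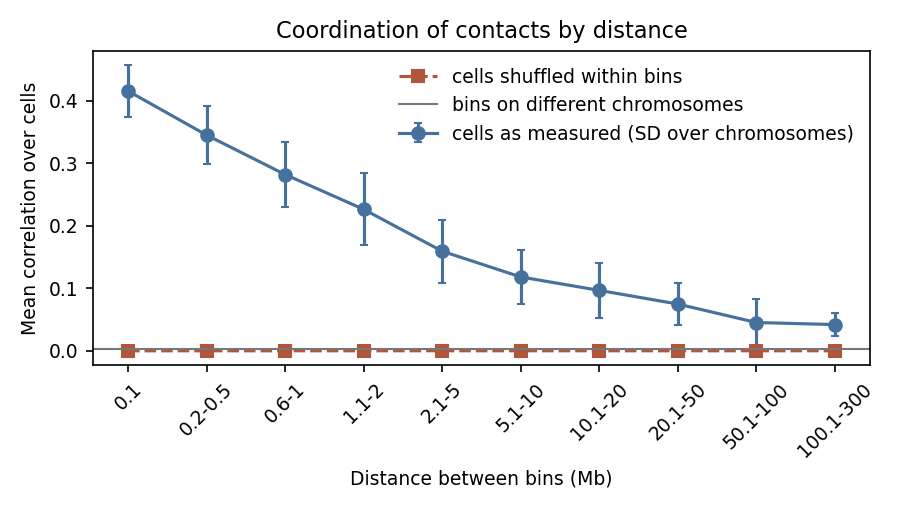
Circles give the mean correlation over 84 cells (vertical axis) of pairs of bins at each distance in Mb (horizontal axis), with the SD over chromosomes, squares the same after shuffling, and the grey line pairs on different chromosomes. The mean falls from 0.415 for adjacent bins to 0.0419 beyond 100 Mb.

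Whole chromosomes varied between cells more than independent bins would. The SD over cells of a chromosome's contact share was a median of 1.49 times the SD after shuffling, with a range from 1.26 on chromosome 11 to 3.52 on chromosome 19, and all 22 chromosomes exceeded all of their 100 shuffles. Chromosome 19 averaged 4.89% in contact but reached 24.0% in its highest cell. The shuffles do not correct for cells whose reads are spread evenly over bins, such as cell 48. Without cells 48, 54 and 56 the median was 1.48, and the quotients of single chromosomes were not examined. After correction for the contact share of the other chromosomes, the 231 correlations between chromosomes had an SD of 0.157, against a median of 0.110 and a highest value of 0.127 in 1000 shuffles. They ranged from -0.395 for chromosomes 6 and 20 to 0.376 for 17 and 22:9, and 2% of the shuffles had a lowest value at least as low and 6.6% a highest value at least as high. The highest value rests on 22:9, which averaged only 1.53% in contact, near the floor. Correlations between chromosomes were not repeated with any cells left out. Reads in bins contacted in under 5% of cells, also examined after seeing the data, moved with the contact share of their chromosome, with a median slope of 0.70 on log scales over 57 cells and a positive slope in 22 of 22 chromosomes.

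In 3 cells several chromosomes had almost no reads. Cell 69 had 312 reads on chromosomes 2, 7, 10, 12, 20 and 21 in its lower-numbered column, or 0.636% of the 49040 expected from the cell's total reads and the median share of these chromosomes over cells. Cell 79 had 3.41% of the expected reads on chromosomes 5, 7, 9:22, 12, 13, 15 and 20, and cell 63 had 0.645% on chromosomes 17 and 21. On these chromosomes the higher-numbered columns held more reads, for example 998 against 115 on chromosome 2 of cell 69. Without these cells the median SD quotient was 1.43 and the correlation of adjacent bins 0.407. This choice of cells was made after seeing the data.

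**Figure D4:**
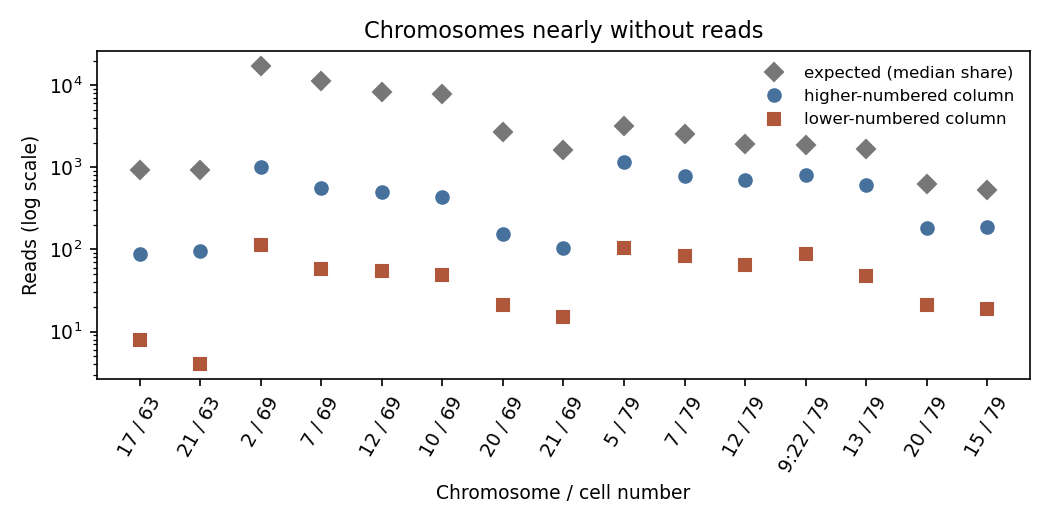
Points give reads on a log scale (vertical axis) for each chromosome and cell with under 5% of the expected reads in cells 63, 69 and 79 (horizontal axis). Squares are the lower-numbered column, circles the higher-numbered column and diamonds the number expected for the lower-numbered column, and on chromosome 2 of cell 69 these are 115, 998 and 17331 reads.

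Gene groups could be placed by chromosome only, since positions within chromosomes were given in another build than the file's. Over 18030 coding genes the mean contact share of the home chromosome was 24.7%. The 19 lists placed were fixed before the data were examined, and their use by chromosome was chosen afterwards. ZNF zinc finger genes stood lowest, with 15.0% over 483 genes, at percentile 1.43 of 10000 rotations of the gene order, and 250 of them are on chromosome 19. Cancer-testis genes, which are normally silent outside the germ line, stood highest with 36.9% over 47 genes (percentile 97.9), 46 of them on X. Keratin-associated proteins had 18.0% (percentile 11.4), olfactory receptors 26.4% (57.7), ribosomal proteins 23.4% (19.2), liver genes 28.5% (95.8), lymphoid genes 24.7% (53.2), and myeloid and progenitor genes 22.7% (14.5). Clustered protocadherins had 33.4% (85.9) and histones 30.9% (77.8). The other lists were glutamate and GABA-A receptors at 26.9% (83.4), taste receptors at 26.9% (57.0), nuclear envelope genes at 26.5% (67.9), cell cycle genes at 26.2% (76.3), neural adhesion genes at 26.1% (74.0), HOX genes at 22.9% (30.0), proteasome subunits at 22.8% (21.1), beta-defensins at 22.2% (25.7) and keratins at 16.6% (11.5). The percentiles describe these chromosome means and are not tests of the genes' own contacts.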

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

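The alternatives by column, read number, cell numbers 1 to 29 or 30 to 86, left-out cells and left-out chromosome 15 were chosen after seeing the data. Of 141 values under the 11 alternatives set before the data were examined, 125 stayed within 1 SD, on the same side of p = 0.05, or, for percents of bins, within 1.5-fold. Of 132 under the 9 added ones, 122 did. The corrected correlation between chromosomes had no stable sign (-0.00267 in odd cells, 0.00969 at a cutoff of 0.5), judged against the SD of pairs at over 20 to 50 Mb. The fall of contact share with gene density held in all 18 alternatives run (r from -0.85 to -0.77), as did the lower ends (difference from -22.1 to -10.9 points). No paired analysis was possible because there is no second group to pair with.

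The percent of bins at 80% or more, 0.303%, was the least stable value. It was 6.20, 0.0114 and 0 at cutoffs of 0.5, 1.5 and 2, 0.492 with each cell divided by its mean, 2.06 with 5 bins averaged, and 0.602 and 1.25 in odd and even cells. It was 0.0265 and 0.909 in the lower- and higher-numbered columns, 0.201 with 168 separate columns, 0.564 at 30000 reads, 0.522 and 1.68 in cells 1 to 29 and 30 to 86, and 0.507 without cells 48, 54 and 56. Fewer cells make a frequency of 80% easier to reach by chance, and beyond that the cause was not tested.

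The contact share per cell was 36.4% at a cutoff of 0.5 and 16.3% at 2, by construction. Averaging 5 bins, which merges neighbours, raised the run quotient to 4.60 and the correlation to 0.822 for adjacent bins and 0.335 at 1.1 to 2 Mb. Without correction for contact share the correlations were 0.461, 0.285 and 0.145 at 0.1, 1.1 to 2 and over 20 to 50 Mb and 0.0769 between chromosomes. Adjacent bins correlated at 0.326 at 30000 reads, 0.337 in cells 1 to 29 and 0.461 in cells 30 to 86, and the cause was not tested.

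Depth limits the calls. In the 61 cells thinned to 30000 reads, contact share was 29.8% ± 5.07 before and 26.8% ± 3.63 after thinning (SD), with 23 shallower cells left out. Not run, for lack of an annotation of the file's build, were all alternatives of gene density across bins and of gene lists.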

Other observations

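The tests of missing chromosomes and of added reads were chosen after the results were seen, as was the choice of cells. For the joined chromosomes, the prediction on the last 7 Mb was set before the data were examined, and that on the last 27 Mb after other results but before its value was computed.

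Cell 48 had reads in 96.6% of covered bins, and its mean ratio in bins contacted in at least 50% of cells was 1.58 times that in bins under 5%, against a median quotient of 28.9 over cells. Cell 54 had a quotient of 2.02. Chromosome 21 of cell 27 had 16 reads where 377 were expected, the only cell with a single chromosome under 5% of expectation. It was left out of the pattern below, and its rarely contacted bins there held 3 reads where 8.74 were expected. Correlations between the 6 pairs of acrocentric chromosomes 13, 14, 15 and 21 averaged -0.0792, against -0.0272 for other pairs.

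The first pattern is the near absence of reads from 6 chromosomes of cell 69, 7 of cell 79 and 2 of cell 63. Bins that rarely touch the lamina held 0.44% of the number set by the other chromosomes of the same cells, and bins contacted in at least 50% of cells held 1.23% of the expected reads. Cell 69 weighs most in both. By cell, the rarely contacted bins held 0.226% in cell 69, 3.11% in cell 79 and 5.25% in cell 63. The bins of at least 50% held 0.631%, 3.61% and 0.618%. The test assumed that chromosomes present but away from the lamina keep reads in rarely contacted bins, but over the other cells these reads fall with contact share (median log slope 0.70). That fit alone would leave 5.90% in cell 69, 11.3% in cell 79 and 29.1% in cell 63, or 262, 36.4 and 5.54 reads where 10, 10 and 1 were found, mostly at contact shares below any in the fit. Missing DNA and chromosomes away from the lamina therefore cannot be told apart by these values, and no other biological explanation was tested.

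The second pattern is the appearance of reads on the same chromosomes in the higher-numbered column. Without a cap on reads per bin, deeper sequencing of the same library would have added reads in proportion to the lower-numbered column. The added reads were at least 20.4 times that number in each of the 3 cells. Recovered reads never exceeded the whole-number expectation of their bin, which had a median of 316. A ratio of 1 in a median bin stood for 9.68 reads in cell 69, 2.66 in cell 79 and 5.75 in cell 63 (deeper column). Typical bins were thus far below this cap, and it does not account for the excess. In these 3 cells the values argue against deeper sequencing of the same library as the only source. Whether the library itself set a lower limit on reads was not tested. Summed over 10 bins, the added reads correlated with the mean profile of the other cells at 0.82 or more. Reads of other cells may be their source, but a cell's own contacts also resemble those of other cells. Log reads of columns that are not a pair correlated at a median of 0.422 in single bins. The added reads were not correlated with the cell's own reads on these chromosomes, so where the excess came from stays open. On chromosome 21 of cell 27 the correlation of added reads with the mean profile was 0.469. A fit of added reads as own plus mean profile gave a median of 8699 reads like the mean profile in the 55 cells from 30 to 86. It gave 1539 in the 29 cells from 1 to 29. These numbers are not scaled by depth, and all cells with at least 100000 reads are among cells 30 to 86. The higher-numbered column also had fewer reads in a median of 10.6% of bins in cells 1 to 29, against 2.02% in cells 30 to 86.

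That fit put 61.2% of the higher-numbered column of cell 56 and 44.1% of that of cell 54 in the mean profile, the cells whose pairs differed most. It cannot separate foreign reads from a flattened own profile in deep columns. Contact share per cell was 26.6% in the lower-numbered columns alone.

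The third pattern concerns the joined chromosomes. If they met the lamina together, the last 27 Mb of 9:22 should have followed the rest of 9:22 more than any other chromosome. The corrected correlation was 0.287, which ranked 7 among 22, below chromosome 17 at 0.499 and above the median of 0.0196, so the hypothesis remains undecided. These 27 Mb had a mean contact share of only 4.22%, also near the floor, so the rank says little. For the last 7 Mb of 22:9 and the rest of 22:9 the correlation was 0.26, within the range from -0.0583 to 0.44 of other chromosome ends, but at a contact share of 0.77% that end was too close to the floor to decide.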
